A study of Homo sapiens with 24 samples.

How the data were processed

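Gene expression was measured with single-colour Illumina bead arrays on total RNA from HOS cells, an established human osteosarcoma line. The 24 arrays form 8 groups of 3: control, bisphenol A (BPA), bisphenol S (BPS) and bisphenol AF (BPAF), each at 8 hours and at 3 months, with every bisphenol at 10 nM. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Array position and hybridisation batch are not given in the sources used here.

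The deposited values were used as log2 expression values, a scale read from the values themselves, which run from 7.061 to 14.334. The submitters' processing notes name lumi 2.10.0, without saying which step it was used for; the transform, background correction and between-array normalization are not given in the sources used here. The array medians of the deposited values lie between 7.368 and 7.376, near the low end of the scale, and the upper quartiles between 8.011 and 8.032. These values are close between arrays but do not tell which steps were applied before deposit. The scale has a floor near its lowest values, and differences of dim probes are compressed by it, so sizes are given as log2 differences and not as folds. Detection p-values were not used here. All 24 columns were used and none was left over.

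Of 47323 probes, 30113 carry 1 gene symbol in the platform annotation, 8 carry several and 17202 carry none. Symbols were updated through the Entrez identifier for 30074 probes, with a RefSeq gene table of assembly GRCh38.p14 used for names only; no coordinates are given because the files name no build. No gene was named from a probe with several symbols, and a probe without a symbol is unnamed here. The 50% of probes with the highest mean over all 24 arrays were tested (23661 probes, mean above 7.362), of which 17483 carry 1 symbol and stand for 12787 genes.

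Group means were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual degrees of freedom and 4.93 prior degrees of freedom), so that all 8 groups share one estimate of the spread per probe. The 18 contrasts were each bisphenol against the control of its exposure time, each pair of bisphenols at one exposure time, the mean of the 3 bisphenols against control, the difference between the 3-month and the 8-hour effect of each bisphenol, and the 3-month control against the 8-hour control. Benjamini-Hochberg adjustment was made over the probes of one contrast, with a threshold of 0.05. Differences are given as log2 values ± the standard error (SE) of the fit, for 3 arrays against 3, and levels as mean ± SD with n = 3. For arrays, their number limits the precision: the median 95% confidence interval reached 0.161 log2 units to either side in a comparison of 2 groups.

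Gene lists on 36 subjects (hormone response, bone, cell division, stress, metabolism, inflammation, matrix, chromatin and markers of other cell types) were written down in advance. The brightest kept probe stood for each gene, and the 33 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 33. Each call was repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Cancer-testis genes (3 measured), skeletal muscle markers (4) and endothelial markers (4) were too few to test.

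The genes named were set by a rule. In each comparison of 2 groups they are, among probes past the threshold with 1 symbol and with every array of one group above every array of the other, the 10 highest and the 10 lowest differences, 1 probe per gene; where fewer than 20 passed, all that passed plus the genes with the smallest unadjusted p, up to 8 in all. With 3 arrays against 3, chance alone separates the groups in this way for 10% of probes. For each list past the camera threshold the 4 genes with the smallest p were taken, and for the estrogen response, nuclear receptor, xenobiotic and osteoblast lists also the 3 genes with the smallest p in each 3-month comparison with control. ESR1, ESR2, ESRRG and GPER1 were to be given at their level in any case; 1 further gene of this rule is not reported here. Any other gene is said to have been chosen after its values were seen.

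Groupings, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to have been added. The alternatives were no filter on dim probes, the brightest 33.3% of probes, quantile normalization, median centring, a fit of only the groups compared, an intensity trend with robust variance, array weights, the replicate number as a block, probes of one gene averaged, and each array left out in turn. A pseudocount does not apply to log2 values. Comparisons with the same controls were set beside 100 simulated sets of unchanged arrays made from the fit's residuals. The procedure was tested on simulated data with 100 probes changed by 0.5 and 100 by 1 log2 unit between BPS and control at 3 months among 23661 probes: 90 and 100 of them were recovered, with 5 false calls. In the simulated comparison of BPA with control at 8 hours, with 0 changed probes, 0 were called. Figures were drawn with matplotlib 3.10.9.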

Results

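HOS cells were exposed to 10 nM of BPA, BPS or BPAF for 8 hours or 3 months, with a control at each time. The bisphenols share a pair of phenol rings and differ in the bridge between them: a carbon with methyl groups in BPA, a sulfonyl group in BPS, and a carbon with trifluoromethyl groups in BPAF. Each of the 8 groups had 3 arrays. Arrays of one group correlated at 0.992 to 0.997 over the 23661 probes tested, and the SD of the difference between such arrays was 0.126 to 0.200 log2 units. The component holding 38.6% of the variance separated the 3-month from the 8-hour arrays, and the next, with 12.4%, spread the 3-month groups from control (14.34 ± 4.40, SD, n = 3) through BPA (3.51 ± 4.90) and BPAF (-5.19 ± 3.26) to BPS (-14.10 ± 6.85).

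**Figure D1:**
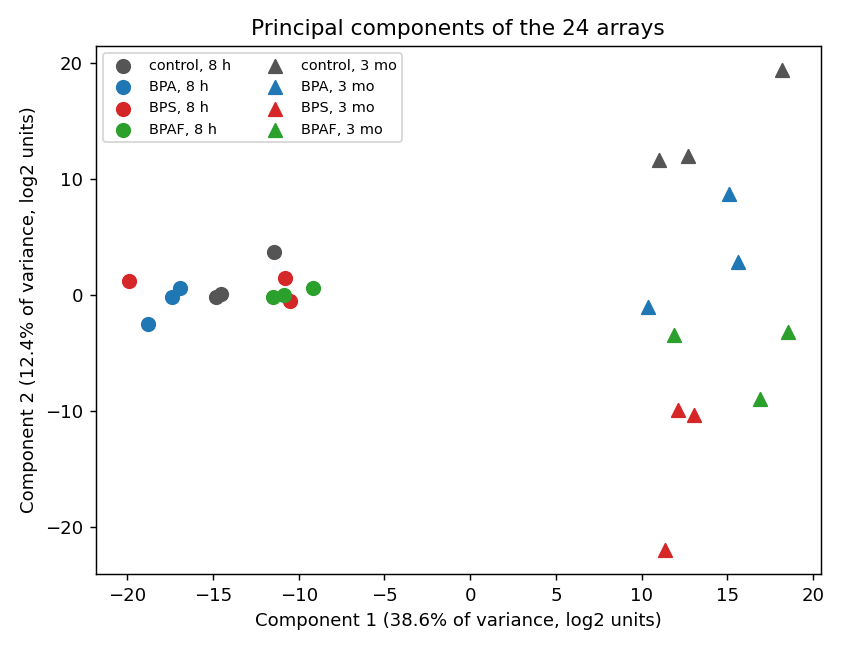
Positions of the 24 arrays on the first and second principal components of the tested probes, in log2 units, with circles for 8 hours, triangles for 3 months and 1 colour per compound (3 arrays per group). The 8-hour groups have means between -0.68 and 1.22 on component 2, while the 3-month groups run from 14.34 for control to -14.10 for BPS.

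The first question was what each bisphenol did within 8 hours. No gene differed from control past the threshold for any of the 3 compounds. The smallest p in the BPA comparison belonged to COA3, a cytochrome c oxidase assembly factor (0.38 ± 0.06, adjusted p = 0.0809), and OPTN had the largest difference among the 8 genes of smallest p (-0.66 ± 0.14, adjusted p = 0.478). For BPS, EIF3L (0.39 ± 0.08) and RPS24 (-0.39 ± 0.09), both of the translation machinery, had adjusted p = 0.814, and for BPAF, ATRX (-0.43 ± 0.08) and IFIT3 (-0.42 ± 0.09) had adjusted p = 0.373. Limma called 0 probes in each comparison, with 1332, 1065 and 1892 probes at an unadjusted p under 0.05 for BPA, BPS and BPAF against 1183 expected by chance. The 95% interval of the difference lay within 0.5 log2 units of 0 for 23173, 23330 and 23114 of the 23661 probes. Many of the probes are dim and their differences are compressed by the floor, which limits this and the later counts of intervals.

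As a list, the 20 genes of cholesterol synthesis lay lower in BPA than in control at 8 hours (median -0.14, camera adjusted p = 9.58e-05), a call that held with an estimated correlation (adjusted p = 0.0351) but not with fry (adjusted p = 0.0623). None of the 20 passed the threshold over all probes and 2 were lower when adjusted over the list alone; INSIG1, a brake on sterol synthesis, differed by -0.42 ± 0.11 and HMGCS1, an early enzyme of the pathway, by -0.38 ± 0.12. Interferon response genes lay higher in BPA (median 0.10) and lower in BPS (median -0.09) and BPAF (median -0.14), with 0 of 40 genes past the threshold in each. The adjusted p with an estimated correlation was 0.711, 0.638 and 0.581. With p adjusted over the list alone, 5 were lower in BPAF and 0 differed in BPA and BPS. The other lists with a camera call at 8 hours also had 0 genes past the threshold and lost the call with an estimated correlation. They were the unfolded protein response (adjusted p = 0.728) and NF-kB lists (adjusted p = 0.711) in BPA, both lower, and mitosis genes in BPAF, lower (adjusted p = 0.581). In BPS, unfolded protein response (adjusted p = 0.556), oxidative phosphorylation (adjusted p = 0.116), NF-kB and smooth muscle lists (both adjusted p = 0.449) lay higher, and ribosomal protein genes (adjusted p = 0.449) lower. When adjusted over the list alone, 2 of the ribosomal protein genes were lower and 0 genes of the other 7 lists differed. Quantile normalization ended the camera calls of the unfolded protein response in BPA (adjusted p = 0.056) and of the ribosomal protein (adjusted p = 0.128, median from -0.06 to -0.01) and smooth muscle lists (adjusted p = 0.112) in BPS. The BPA count was 5 without control replicate 1, 1 without the 4 arrays farthest from their group means (an alternative added after seeing the data) and 1 with the probes of a gene averaged. The BPAF count was 3 without BPAF replicate 2.

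After 3 months of BPA, 101 probes differed from the 3-month control, 38 higher and 63 lower. NPPB rose most, the gene of the B-type natriuretic peptide, at 12.36 ± 0.17 against 11.45 ± 0.37 (a difference of 0.91 ± 0.16, adjusted p = 0.0142). The monoamine oxidase gene MAOA (0.78 ± 0.16) and the fibrillar collagen gene COL11A1 (0.77 ± 0.15) rose as well, as did ID3 (0.74 ± 0.13) and ID1 (0.60 ± 0.11), inhibitors of helix-loop-helix transcription factors. GREM1, an antagonist of bone morphogenetic proteins, rose by 0.62 ± 0.11, and STOX2 and RPS7 by 0.60 ± 0.11 and 0.55 ± 0.12. The RPS7 probe may not tell that gene from near-identical copies. The lowest was TXNIP, a thioredoxin inhibitor that responds to glucose (-1.04 ± 0.15, adjusted p = 0.00338). Next among the genes named were RIPOR3 (-0.82 ± 0.12), the chemokine gene CCL2 (-0.81 ± 0.16), UBE2L6, which conjugates ISG15 (-0.81 ± 0.14), the MYC antagonist MXD4 (-0.80 ± 0.17) and the collagen gene COL5A1 (-0.72 ± 0.14). CRABP2, PLAAT4, SHISA2 and the guanylate-binding protein gene GBP2 fell by 0.68 to 0.71.

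Of 27 genes of the unfolded protein response and the ATF4 pathway, 4 rose and 0 fell under BPA (8 higher adjusted over the list alone), with a list median of 0.19. The adjusted p was 1.25e-07 by camera, 0.158 with an estimated correlation and 0.0208 with fry. They were TRIB3 (0.64 ± 0.14), SDF2L1 (0.59 ± 0.12), CRELD2 (0.45 ± 0.08) and MANF (0.38 ± 0.08), the last 3 encoding proteins of the endoplasmic reticulum. Of 40 interferon response genes 3 fell (4 lower adjusted over the list alone): IRF1 (-0.45 ± 0.09), the RNA sensor gene IFIH1 (-0.58 ± 0.13) and PSMB9 of the immunoproteasome (-0.42 ± 0.09). The list's camera call was lost with an estimated correlation (adjusted p = 0.343). Among 34 extracellular matrix genes, COL11A1 rose and COL5A1 and FBLN5 (-0.32 ± 0.07) fell (1 higher and 3 lower adjusted over the list alone), and among 27 NF-kB genes CCL2 alone passed (1 lower adjusted over the list alone), with an adjusted p of 0.343 with an estimated correlation for both lists. The metallothionein list (0 of 8, or 1 lower adjusted over the list alone) and ribosomal protein genes (0 of 40 by either adjustment) also lay lower by camera, again with an adjusted p of 0.343 with an estimated correlation. The ribosomal protein call ended after quantile normalization (median from -0.08 to -0.03, adjusted p = 0.413).

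The BPA count was sensitive to single arrays and to the fit: it was 22 and 24 without control replicates 2 and 3, and 50, 11 and 53 without BPA replicates 1, 2 and 3. It was 21 when only BPA and control were fitted, 55 without the filter on dim probes, 253 with array weights, and 176 without the 4 arrays farthest from their group means, an alternative added after seeing the data.

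After 3 months of BPS, 2716 probes differed from control, 1242 higher (964 genes) and 1474 lower (1120 genes). NPPB reached 12.94 ± 0.21 against 11.45 ± 0.37 in control (adjusted p = 9.38e-06). ID3 (1.42 ± 0.13), MAOA (1.36 ± 0.16) and ID1 (1.09 ± 0.11) also rose. Others were the calcium channel gene TRPC6 (1.45 ± 0.26), RIOK1 (1.27 ± 0.30), the oxidized lipoprotein receptor gene OLR1 (1.24 ± 0.18), the desmosome gene DSP (1.24 ± 0.30), SOX3 (1.07 ± 0.14) and MSANTD2 (1.06 ± 0.23). TXNIP fell from 9.83 ± 0.22 to 8.42 ± 0.23 (-1.41 ± 0.15, adjusted p = 1.13e-05). CCND2, the gene of cyclin D2 (-1.39 ± 0.18), LOXL4, a collagen-crosslinking enzyme (-1.35 ± 0.19), and KRCC1 (-1.24 ± 0.09), with the smallest adjusted p of the comparison (2.89e-07), were lower too. SYTL2 (8.96 ± 0.59 against 10.26 ± 0.07), the type I collagen gene COL1A2 (-1.24 ± 0.22), RIPOR3 (-1.22 ± 0.12), LRRC17 (-1.21 ± 0.22), S100A4 (-1.19 ± 0.21) and GAS1, known from growth arrest (-1.16 ± 0.15), fell as well.

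Of 34 extracellular matrix genes 16 fell and 1 rose under BPS (18 and 1 adjusted over the list alone). The list median was -0.30, with an adjusted p of 4.32e-08 by camera at the preset correlation and 0.282 with an estimated correlation. COL5A1 (-1.09 ± 0.14), COL6A3 (-0.93 ± 0.14) and COL7A1 (-0.59 ± 0.10) were lower, while COL11A1 rose by 0.98 ± 0.15. Of 40 interferon response genes 11 fell and 0 rose (14 lower adjusted over the list alone), among them IFIH1 (-0.77 ± 0.13), SAMD9 (-0.66 ± 0.12), PSMB8 (-0.66 ± 0.13) and IRF1 (-0.63 ± 0.09). Their adjusted p was 0.282 with an estimated correlation. Of 39 DNA replication genes 8 rose and 0 fell (13 higher adjusted over the list alone), with MCM2 at 0.67 ± 0.16, GINS2 at 0.56 ± 0.11, MCM4 at 0.46 ± 0.09 and FEN1 at 0.38 ± 0.07. The adjusted p with an estimated correlation was again 0.282.

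A further 6 lists had a camera call under BPS. Mitosis genes (4 of 40 higher; AURKB 0.54 ± 0.13, AURKA 0.32 ± 0.07), heat shock genes (5 of 19 higher; HSP90AB1 0.50 ± 0.09, CHORDC1 0.49 ± 0.10) and cholesterol synthesis genes (4 of 20 higher; EBP 0.96 ± 0.14, DHCR7 0.59 ± 0.10) lay higher, with an adjusted p of 0.434, 0.282 and 0.282 with an estimated correlation. So did immediate early genes (4 of 25 higher; DUSP5 0.84 ± 0.12, CCN2 0.73 ± 0.14, DUSP1 0.52 ± 0.11) and smooth muscle markers (2 of 10 higher; CSRP1 0.52 ± 0.10, TAGLN 0.34 ± 0.06), with an adjusted p of 0.283 and 0.282 with an estimated correlation. NF-kB genes lay lower, with 4 of 27 lower and 1 higher, including the chemokine genes CCL2 (-1.07 ± 0.16) and CXCL1 (-1.01 ± 0.27), and an adjusted p of 0.283 with an estimated correlation. Adjusted over the list alone, 8 mitosis genes were higher and 2 lower, 6 cholesterol synthesis genes higher and 1 lower, and 1 NF-kB gene higher and 8 lower. In the same way, 6 heat shock, 4 immediate early and 4 smooth muscle genes were higher. After quantile normalization the mitosis and smooth muscle calls ended (adjusted p = 0.058 and 0.0528). Fry called 14 of the 33 lists under BPS, which need not include all those called by camera. The BPS count was 1321 without control replicate 2, 1540 without BPS replicate 1 and 1662 when only BPS and control were fitted. It was 520 without the 4 most deviating arrays, where BPAF against control had 1485; that fit leaves 1 BPS array at 3 months, assumed to vary like the other groups.

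After 3 months of BPAF, 1100 probes differed from control, 470 higher and 630 lower. NPPB (1.28 ± 0.16, adjusted p = 0.000231) and RIOK1 (1.28 ± 0.30) rose most, with TRPC6 (1.26 ± 0.26), MAOA (1.17 ± 0.16), COL11A1 (1.11 ± 0.15) and OLR1 (1.05 ± 0.18) next. CCN2, the gene of connective tissue growth factor (0.94 ± 0.16), C4BPB (0.91 ± 0.21), MSANTD2 (0.91 ± 0.23) and ID1 (0.90 ± 0.11) followed. TXNIP was the lowest (-1.50 ± 0.15, adjusted p = 3.47e-05). Also lower were MXD4 and UBE2L6 (-1.06 ± 0.17 and -1.06 ± 0.14), LOXL4 (-1.04 ± 0.19), S100A4 (-0.99 ± 0.21), COL1A2 on another probe than in BPS (-0.97 ± 0.27) and RIPOR3 (-0.93 ± 0.12). NBPF9, SNORA79 and SNAR-A1, at -1.08 ± 0.26, -0.94 ± 0.20 and -0.93 ± 0.24, belong to multicopy families whose members a probe may not tell apart.

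Metallothioneins are cysteine-rich metal-binding proteins. Of 8 measured genes of their list, which also holds SLC30A1, 3 fell under BPAF (MT1F -0.59 ± 0.13, MT1G -0.57 ± 0.11, MT1H -0.45 ± 0.08). The list had an adjusted p of 0.184 with an estimated correlation. With p adjusted over the list alone, 3 were lower and 1 higher. Of 26 chromatin and DNA methylation enzymes 3 rose (3 adjusted over the list alone): the DNA methyltransferase gene DNMT3B (0.51 ± 0.11), the Polycomb gene SUZ12 (0.41 ± 0.09) and TET1 (0.37 ± 0.09). Of 40 interferon response genes 9 fell and 0 rose (15 lower adjusted over the list alone), with IRF1 at -0.80 ± 0.09 and IFI6 at -0.53 ± 0.12. The adjusted p with an estimated correlation was 0.184 for the chromatin and the interferon lists. Of 34 matrix genes 5 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), with COL6A3 at -0.83 ± 0.14, COL5A1 at -0.82 ± 0.14 and BGN at -0.53 ± 0.10. Higher by camera were cholesterol synthesis (4 of 20; HMGCS1 0.70 ± 0.12, MSMO1 0.52 ± 0.12) and heat shock genes (3 of 19; CHORDC1 0.54 ± 0.10), with an adjusted p of 0.125 and 0.184 with an estimated correlation. So were immediate early genes (4 of 25; DUSP5 0.78 ± 0.12, EGR1 0.62 ± 0.11), and smooth muscle markers (3 of 10; CNN1 0.49 ± 0.10), both with an adjusted p of 0.184 with an estimated correlation. Mitosis (2 of 40; NUF2 0.36 ± 0.09, AURKA 0.33 ± 0.07) and DNA replication genes (2 of 39) lay higher, the latter with PCNA at 0.34 ± 0.08 and MCM6 at 0.26 ± 0.07, while ORC6 fell (-0.40 ± 0.10). Their adjusted p was 0.184 and 0.322 with an estimated correlation. NF-kB genes (2 of 27 lower; IL32 -0.62 ± 0.12), nuclear receptors (2 of 17) and ribosomal protein genes (0 of 40) lay lower by camera, with an adjusted p of 0.322, 0.184 and 0.184 with an estimated correlation. When adjusted over the list alone, 7 cholesterol synthesis, 7 immediate early and 2 mitosis genes were higher, 4 nuclear receptor genes were lower, and 0 ribosomal protein genes differed. The heat shock (5 higher), DNA replication and smooth muscle lists (4 higher each) then had 1 lower gene each, and the NF-kB list 6 lower and 1 higher. The ribosomal protein call ended after quantile normalization (median from -0.14 to -0.07, adjusted p = 0.104). Under BPAF, fry called 14 of the 33 lists, which need not include all those called by camera. The BPAF count was 362 and 656 without control replicates 2 and 3, 410 and 632 without BPAF replicates 2 and 3, and 686 without the filter on dim probes.

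**Figure D2:**
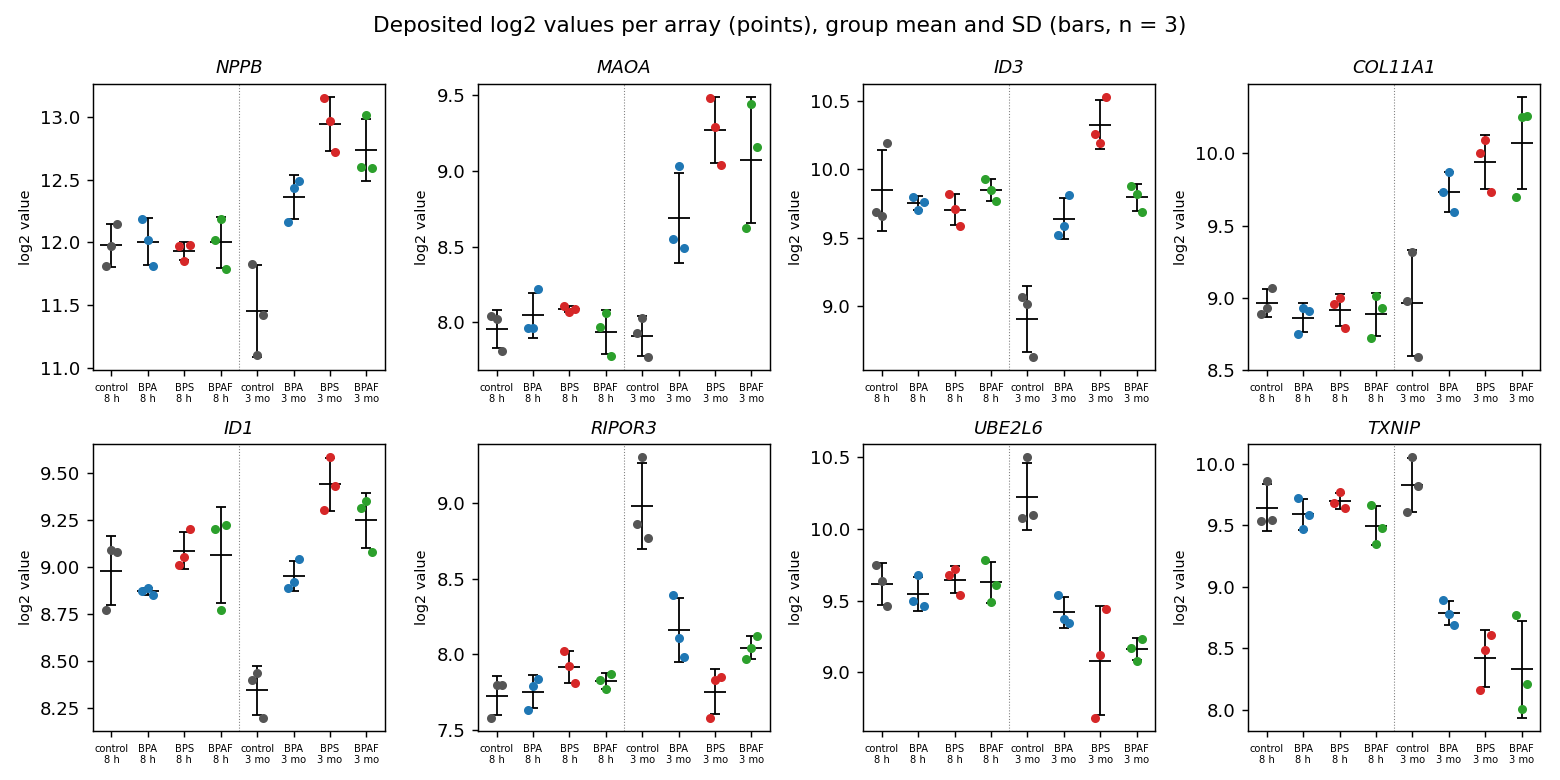
Deposited log2 values of 8 genes in each array (points), with the group mean and SD (bars, n = 3), for the 8 groups; the dotted line parts 8 hours from 3 months. TXNIP averages 9.83 in the 3-month control and 8.79, 8.42 and 8.33 after 3 months of BPA, BPS and BPAF, and NPPB averages 11.45 in that control and 12.36, 12.94 and 12.73 in the treated groups.

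The 3 compounds shared many of their calls at 3 months. Probes past the threshold in all 3 comparisons numbered 25 higher and 55 lower, and 0 probes were called in opposite directions by any pair. NPPB, MAOA, COL11A1, ID1 and ID3 rose, and TXNIP, RIPOR3, CCL2, COL5A1, IRF1 and IFIH1 fell, in each comparison. Other probes for ID1 (7.36 in control) and RIPOR3 (7.49 in control) lay near the floor and did not pass. BPS and BPAF shared 299 higher and 495 lower probes, where independent lists of these sizes would share 24.7 and 39.2. BPA shared 27 and 60 with BPS (1.99 and 3.92 for independent lists) and 27 and 57 with BPAF (0.755 and 1.68). The comparisons use the same 3 control arrays. The correlation across probes, which are not independent replicates, was 0.66 for BPA and BPS, 0.76 for BPA and BPAF and 0.78 for BPS and BPAF. Simulated unchanged groups against those controls gave 0.50, 0.50 and 0.49. The covariances of 0.0146, 0.0136 and 0.0231 stood beside simulated means of 0.00416, 0.00410 and 0.00401, which leaves differences of 0.0104, 0.00950 and 0.0191. Controls of 3 arrays cannot be split with 2 in each part, so part of the excess in shared calls may come from the shared controls.

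At 8 hours the corresponding correlations were 0.37 (BPA and BPS), 0.15 (BPA and BPAF) and 0.35 (BPS and BPAF), and the simulated ones 0.49, 0.48 and 0.51, with 0 shared calls. The covariances were 0.00303, 0.00143 and 0.00307 beside simulated means of 0.00415, 0.00400 and 0.00435, each within the range of the 100 simulated sets.

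Because bisphenols are known as weak estrogens, receptors and their target genes were examined separately. Every probe for the estrogen receptor genes ESR1 and ESR2 and for the estrogen-related receptor gene ESRRG lay below the brightness limit, with means over all arrays of 7.26 to 7.32, at the floor of the scale, so their levels could not be compared. The membrane estrogen receptor gene GPER1 was measured by 3 probes with means of 7.38, 8.11 and 8.41. The 17 measured estrogen response genes passed camera in none of the 3-month comparisons with control (adjusted p = 0.700 for BPA, 0.678 for BPS and 0.995 for BPAF). CCND1, the gene of cyclin D1, rose under BPS (0.35 ± 0.07) and BPAF (0.27 ± 0.07) and NRIP1 fell under BPS (-0.31 ± 0.10), while under BPA the smallest p was that of ABCA3 (-0.22 ± 0.08, adjusted p = 0.289). Adjusted over the list alone, 2 genes were higher and 1 lower under BPS and under BPAF, and 0 differed under BPA.

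Of 17 nuclear receptor genes, THRA fell under BPS and BPAF (both -0.35 ± 0.07). The glucocorticoid receptor gene NR3C1 (-0.33 ± 0.08) and the dioxin receptor gene AHR (-0.37 ± 0.12) fell under BPS, and RXRB under BPAF (-0.32 ± 0.08). Under BPA, RXRA differed by -0.26 ± 0.08 (adjusted p = 0.167). With p adjusted over the list alone, 1, 4 and 4 receptor genes were lower under BPA, BPS and BPAF. CYP1B1, a target of AHR, fell under BPS (-0.73 ± 0.20), the 1 of 7 xenobiotic genes to pass there, and none passed under BPA or BPAF. When adjusted over the list alone, 1 was lower under BPA, 2 were lower and 1 higher under BPS, and 0 differed under BPAF. The osteoblast and bone matrix list of 22 genes did not pass as a list in any of the 3 (adjusted p = 0.662, 0.638 and 0.939 for BPA, BPS and BPAF). ID1 and ID3 were its 2 higher genes under each compound. Counted on the brightest probe of each gene, 5 of its genes fell under BPS, COL1A2 among them, and 1 under BPAF, ENPP1 (-0.44 ± 0.10). COL1A2 also passed as lower under BPAF, but on a probe that the list does not use. Adjusted over the list alone, 2 were higher under each compound, with 0, 5 and 2 lower under BPA, BPS and BPAF. Lists on steroid hormone synthesis, Wnt, p53, NRF2, hypoxia, matrix proteases, growth factors and apoptosis had no camera call in any of the 18 comparisons. The same held for the chondrocyte, epithelial, neural and osteoclast marker lists.

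**Figure D3:**
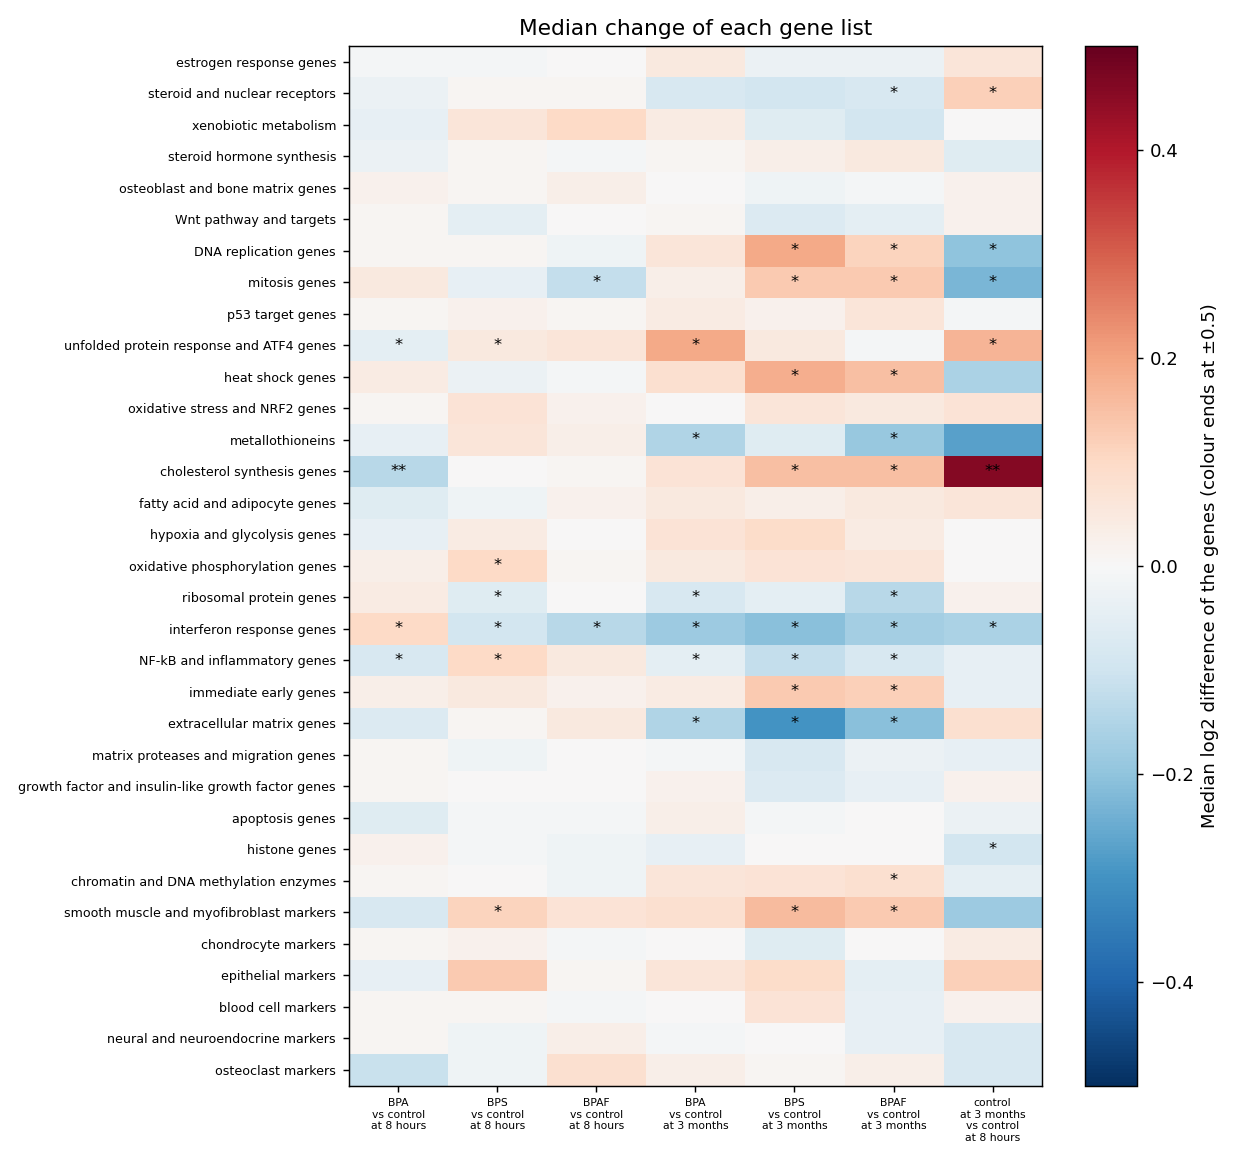
Median log2 difference of the measured genes of the 33 tested lists (rows) in 7 comparisons (columns), with red for higher and blue for lower in the group named first. A single asterisk is a camera call at the preset correlation and a double one a call that also held with an estimated correlation, as for cholesterol synthesis genes, with a median of 0.46 between the controls of 3 months and 8 hours and of -0.14 for BPA at 8 hours.

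Set directly against each other at the same dose, BPAF and BPA differed at 8 hours in 57 probes, 23 higher and 34 lower in BPAF. Among the lower ones were the interferon-induced genes IFIT1 (-1.01 ± 0.21) and the antiviral GTPase gene MX1 (9.95 ± 0.08 against 10.94 ± 0.09, -0.99 ± 0.16, adjusted p = 0.00761). Others were ISG15 (-0.83 ± 0.15), IFI44 (-0.82 ± 0.16), OAS2 (-0.66 ± 0.11), IFI6 (-0.61 ± 0.12), IFIT3 (-0.60 ± 0.09) and SAMD9 (-0.58 ± 0.12). DYRK2 (-0.69 ± 0.10) and OSBPL8 (-0.67 ± 0.14) were lower too. Higher in BPAF were ASS1, an enzyme of arginine synthesis (0.61 ± 0.11), ANXA2P1 (0.60 ± 0.11), C2orf69 (0.60 ± 0.09), PAPSS1 (0.59 ± 0.12) and MED7 (0.52 ± 0.11), whose difference was -0.02 when its probes were averaged. RBCK1 (0.51 ± 0.09), BIRC6 (0.46 ± 0.08), CD276 (0.43 ± 0.08), ALDH5A1 (0.42 ± 0.09) and MESP1 (0.41 ± 0.08) were also higher. Of 40 interferon response genes 11 were lower and 0 higher in BPAF (20 adjusted over the list alone), with an adjusted p of 3.25e-14 by camera, 0.00596 by fry and 0.0796 with an estimated correlation. MX1 stood at 10.48 ± 0.49 (SD, n = 3) in the control, and neither compound differed from that control past the threshold. The count was 15, 31 and 31 without BPA replicates 1, 2 and 3 and 27, 157 and 11 without BPAF replicates 1, 2 and 3. It was 31 without the filter, 116 with the brightest 33.3% of probes and 158 with an intensity trend and robust variance.

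Cholesterol synthesis genes lay higher in BPAF than in BPA at 8 hours (median 0.14, adjusted p = 8.28e-07, and 0.00747 with an estimated correlation), with 0 of 20 past the threshold over all probes and 9 higher adjusted over the list alone; CYP51A1 differed by 0.55 ± 0.12 (adjusted p = 0.0548). They also lay higher in BPS than in BPA (median 0.09, adjusted p = 0.000107, and 0.0483 with an estimated correlation). With p adjusted over the list alone, 1 was then higher. These calls and that of BPA against control rest on the same 3 BPA arrays. Against control, cholesterol synthesis genes had no camera call at 8 hours in BPS (median 0, adjusted p = 0.983) or BPAF (median 0.01, adjusted p = 0.169). Interferon response genes lay lower in BPS than in BPA as well (0 of 40 past the threshold, 17 lower and 1 higher adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). The other lists with a camera call among the 3 pairs of compounds at 8 hours had 0 genes past the threshold and lost the call with an estimated correlation (adjusted p between 0.0712 and 0.922). Of these, quantile normalization ended the oxidative phosphorylation and ribosomal protein calls between BPS and BPA (both adjusted p = 0.190) and the smooth muscle call between BPAF and BPA (adjusted p = 0.163).

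Limma called 0 probes between BPS and BPA at 8 hours (1651 at an unadjusted p under 0.05) and 0 between BPAF and BPS (2205), the smallest p being those of ERLEC1 (0.37 ± 0.07, adjusted p = 0.147) and SNAPIN (0.43 ± 0.08, adjusted p = 0.280). The first count was 11 without BPS replicate 1, 1 with only the groups compared, 5 with an intensity trend and robust variance, and 15 without the 4 most deviating arrays. The second was 1 without BPAF replicate 2. Intervals lay within 0.5 log2 units of 0 for 23074 probes between BPS and BPA and for 22941 between BPAF and BPS.

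At 3 months BPS and BPA differed in 432 probes, 162 higher and 270 lower in BPS. Lower in BPS were INHBE (-1.05 ± 0.16) and NIBAN1 (9.57 ± 0.03 against 10.40 ± 0.13, -0.83 ± 0.09, adjusted p = 0.000111). A second NIBAN1 probe had means of 10.15 in BPS and 10.55 in BPA. Others were LOXL4 (-0.80 ± 0.19), SYTL2 (-0.82 ± 0.19), SEMA3C (-0.72 ± 0.17), the actin-binding gene CALD1 (-0.72 ± 0.08), ARID4B (-0.68 ± 0.12), CEP290 (-0.64 ± 0.09) and the multicopy NBPF9 and NBPF10 (-1.02 ± 0.26 and -0.95 ± 0.16). SOX3 (0.80 ± 0.14), SFTA1P (0.71 ± 0.15), ID3 (0.69 ± 0.13), the sterol isomerase gene EBP (0.68 ± 0.14), NRGN (0.66 ± 0.14), AP1M2 (0.65 ± 0.14) and TUBB4B (0.65 ± 0.15) were higher in BPS. So were the neuronal intermediate filament gene INA (0.62 ± 0.10), RBM38 (0.60 ± 0.14) and MFAP5 (0.58 ± 0.13). Unfolded protein response genes lay lower in BPS than in BPA (2 of 27, DDIT3 at -0.48 ± 0.11 and CRELD2 at -0.34 ± 0.08; 9 adjusted over the list alone), with an adjusted p of 0.225 with an estimated correlation. DNA replication genes lay higher (3 of 39; MCM5 0.44 ± 0.11, FEN1 0.43 ± 0.07, POLD1 0.30 ± 0.07; 10 higher and 1 lower adjusted over the list alone). Their adjusted p with an estimated correlation was 0.366. Matrix genes (1 of 34 lower, COL5A2 at -0.58 ± 0.12), heat shock genes (0 of 19) and blood cell markers (1 of 6 higher, the globin gene HBA2 at 0.54 ± 0.12) had an adjusted p of 0.394, 0.366 and 0.225 with an estimated correlation. The HBA2 probe may not tell that gene from a near-identical copy. When adjusted over the list alone, 10 matrix genes were lower and 1 heat shock gene and 2 blood cell markers higher. The count of 432 was 0 when only BPS and BPA were fitted, and 11 and 126 without BPA replicates 1 and 2. It was 101 without BPS replicate 1, 196 without the filter, 654 with array weights and 10 without the 4 most deviating arrays.

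BPAF and BPA differed at 3 months in 2 probes, both lower in BPAF: NIBAN1 (-0.76 ± 0.09, adjusted p = 0.00139), with the second probe at 10.31 in BPAF and 10.55 in BPA, and CRELD2 (-0.51 ± 0.08, adjusted p = 0.0170). The unfolded protein response list lay lower in BPAF (median -0.17, adjusted p = 2.16e-10 by camera, 0.0429 with an estimated correlation and 0.0132 with fry). CRELD2 alone passed, and 7 of 27 were lower adjusted over the list alone. TRIB3 differed by -0.60 ± 0.14 and SDF2L1 by -0.54 ± 0.12 (both adjusted p = 0.201). Mitosis (adjusted p = 0.231 with an estimated correlation), cholesterol and immediate early genes (0.230 each) and DNA replication genes (0.635) lay higher and matrix genes (0.649) lower, with 0 genes past the threshold in each. Adjusted over the list alone, 3 immediate early genes were higher and 0 genes of the other 4 lists differed. The count of 2 was 1 without BPA replicate 2 or BPAF replicate 2, 15 without BPA replicate 3 and 10 without BPAF replicate 1. It was 0 with only the groups compared, 4 with an intensity trend and robust variance, 5 with array weights and 1 without the 4 most deviating arrays.

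Between BPAF and BPS at 3 months 7 probes differed, 2 of them unnamed here. Higher in BPAF were CCND2 (9.19 ± 0.25 against 8.11 ± 0.33, 1.08 ± 0.18), GOLGA8B (0.61 ± 0.11), VPS13A (0.54 ± 0.08) and the repair gene XRCC4 (0.47 ± 0.08), and lower was ILK, the integrin-linked kinase gene (-0.41 ± 0.07), with adjusted p of 0.0210 for VPS13A and 0.0467 for the other genes. DNA replication and ribosomal protein genes lay lower in BPAF and matrix genes higher (adjusted p = 0.790 each with an estimated correlation), and blood cell markers lower (adjusted p = 0.203), with 0 genes past the threshold. With p adjusted over the list alone, 2 DNA replication genes and 1 blood cell marker were lower and 2 matrix genes higher. The ribosomal protein call ended after quantile normalization (adjusted p = 0.193). The 95% interval lay within 0.5 log2 units of 0 for 23007 probes between BPAF and BPA and 22619 between BPAF and BPS, so differences above that size were left open for the remainder. The count of 7 was 0, 23 and 4 without BPS replicates 1, 2 and 3 and 26, 1 and 0 without BPAF replicates 1, 2 and 3. It was 0 with only the groups compared, 1 without the filter on dim probes, 3 after quantile normalization and 1 without the 4 most deviating arrays.

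**Figure D4:**
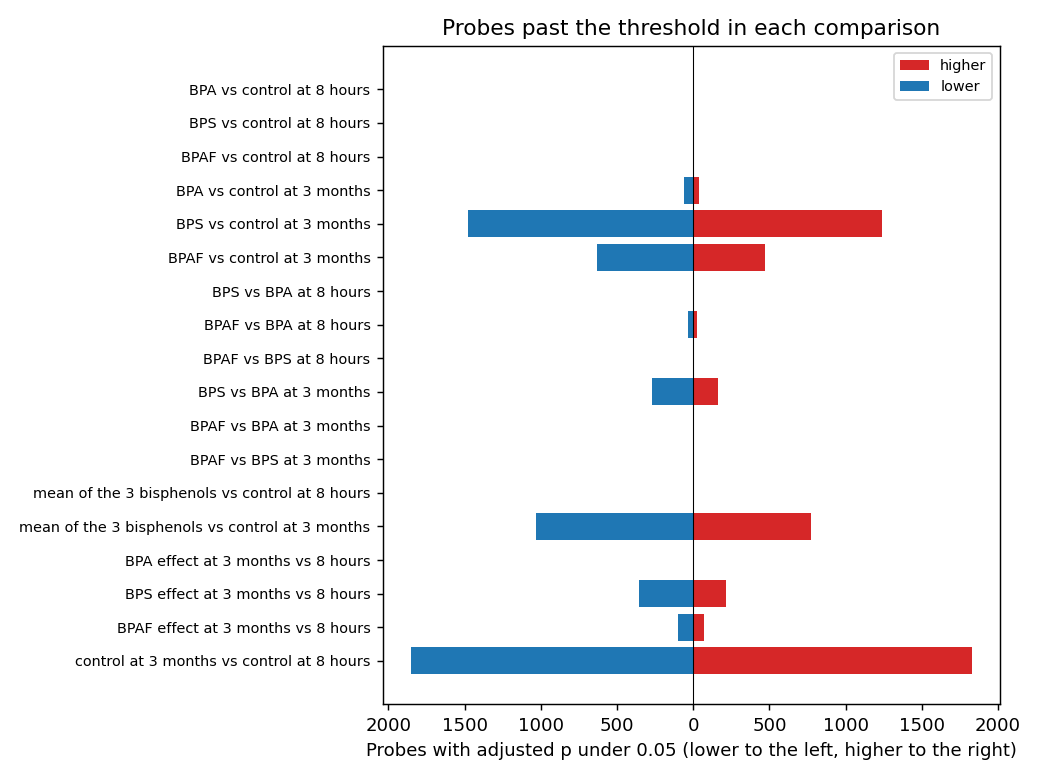
Number of probes past an adjusted p of 0.05 in each of the 18 comparisons, with those lower in the group named first drawn to the left and those higher to the right of 0. The bars are longest for the 3-month control against the 8-hour control (1850 lower and 1827 higher) and for BPS against control at 3 months (1474 lower and 1242 higher), and no probe was called for any compound against control at 8 hours.

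Averaged over the 3 compounds, 0 probes differed from control at 8 hours with limma (1040 at an unadjusted p under 0.05), and 1802 did at 3 months, 774 higher and 1028 lower. The 14 lists called at 3 months included matrix genes (14 lower and 1 higher of 34, or 18 and 1 adjusted over the list alone; median -0.25) and interferon response genes (12 lower of 40, or 17 adjusted over the list alone; median -0.21). All 14 calls were lost with an estimated correlation (adjusted p between 0.198 and 0.324), and those of the oxidative phosphorylation, ribosomal protein and chromatin lists also after quantile normalization (adjusted p = 0.657, 0.409 and 0.101). Fry, which compares no list with other genes, called 17 of the 33 lists for the mean at 3 months. For BPA against control at 3 months it called 1, where camera called 6. The 8-hour count was 1 without control replicate 1, and the 3-month count was 1147, 492 and 1009 without control replicates 1, 2 and 3.

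Tested directly, the effect at 3 months differed from that at 8 hours for 569 probes with BPS, 170 with BPAF and 1 with BPA. With BPS and BPAF the genes given were chosen among those named at 3 months, which favours large changes of effect. TXNIP had a difference from control of 0.05 ± 0.15 with BPS and -0.15 ± 0.15 with BPAF at 8 hours. The change in its effect was -1.47 ± 0.22 (adjusted p = 0.00194) and -1.36 ± 0.22 (adjusted p = 0.00838). NPPB had a difference of effects of 1.54 ± 0.23 with BPS and 1.26 ± 0.23 with BPAF, and ID3 of 1.56 ± 0.18 with BPS (adjusted p = 0.000157). With BPA the probe was that of MSRB2, a methionine sulfoxide reductase gene (-0.87 ± 0.12, adjusted p = 0.00643), named after its value was seen. The BPS count was 291 and 300 without 8-hour control replicates 1 and 3, 336 and 343 without 8-hour BPS replicates 1 and 2, 192 without 3-month control replicate 2, 233 without 3-month BPS replicate 1, 325 without the filter, 314 with only the groups compared and 30 without the 4 most deviating arrays. The BPAF count was 36 and 86 without 8-hour control replicates 1 and 3, 67 and 75 without 8-hour BPAF replicates 1 and 3, 31 and 98 without 3-month control replicates 2 and 3, 262, 28 and 87 without 3-month BPAF replicates 1, 2 and 3, 65 without the filter and 113 with only the groups compared, and the BPA count reached 7 without 3-month BPA replicate 3, 3 without 3-month control replicate 2, and 2 without 8-hour control replicate 1 or 8-hour BPA replicate 1 or 2.

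The controls of 8 hours and 3 months also differed from each other, in 3677 probes, 1827 higher and 1850 lower at 3 months. Among the genes named, the stress-induced gene DDIT4 rose most (9.40 ± 0.47 to 11.15 ± 0.29, 1.75 ± 0.24). It was followed by the retinoid enzyme gene DHRS3 (1.65 ± 0.13), LOXL4 (1.64 ± 0.19), the troponin gene TNNC1 (1.60 ± 0.11) and QPRT (1.54 ± 0.16). Asparagine synthetase, ASNS (1.52 ± 0.14), INHBE (1.39 ± 0.16), MAMDC2 (1.32 ± 0.17), LAD1 (1.28 ± 0.08) and RIPOR3 (1.25 ± 0.12) came next. SPOCD1 (-1.60 ± 0.12), the collagenase gene MMP1 (-1.44 ± 0.22), ISG15 (-1.39 ± 0.15) and VGF (-1.32 ± 0.10) fell most. IFI44 (-1.26 ± 0.16), UBASH3B (-1.16 ± 0.09), the tenascin gene TNC (-1.16 ± 0.10), SRGN (-1.14 ± 0.11), GLIPR1 (-1.06 ± 0.13) and the galanin gene GAL (-1.02 ± 0.14) followed. Of 20 cholesterol synthesis genes 15 rose (16 adjusted over the list alone; median 0.46), including CYP51A1 (0.87 ± 0.12) and INSIG1 (0.84 ± 0.11). The call held with an estimated correlation (adjusted p = 0.000320). Mitosis genes (17 of 40 lower; HMMR -0.59 ± 0.08), DNA replication genes (17 of 39 lower; GINS2 -0.58 ± 0.11, CCNE1 -0.56 ± 0.08), interferon response genes (15 of 40 lower; IRF7 -0.57 ± 0.07) and histone genes (5 of 25 lower; H2AX -0.60 ± 0.13) lay lower by camera. Their adjusted p was 0.0843, 0.151, 0.292 and 0.292 with an estimated correlation. Nuclear receptors (7 of 17 higher; RARB 0.75 ± 0.11, PPARG 0.56 ± 0.12) and unfolded protein response and ATF4 genes (8 of 27 higher, 1 lower; PHGDH 0.71 ± 0.09) lay higher (adjusted p = 0.0785 and 0.184 with an estimated correlation). When adjusted over the list alone, 22 mitosis, 20 DNA replication, 16 interferon response and 5 histone genes were lower, 7 nuclear receptor genes higher, and 9 unfolded protein response genes higher and 1 lower. Between these controls fry called 14 of the 33 lists, where camera called 7. Exposure time cannot be told apart here from any array batch that follows it, and the count of probes was 2135 without 3-month control replicate 2.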

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

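The test of which splits kept the 3-month arrays in their true groups was chosen only after the count of splits had been seen, and the other tests were planned. A difference between the exposure times marked the results of this paragraph, each given as the effect of a compound at 3 months minus its effect at 8 hours. It reached the threshold for 569 probes with BPS, 170 with BPAF and 1 with BPA. With BPS, the effect of ID3 differed by 1.56, NPPB by 1.54, TRPC6 by 1.43, MAOA by 1.23, OLR1 by 1.12, SOX3 by 1.08 and ID1 by 0.98. On the other side stood LOXL4 (-1.48), TXNIP (-1.47), RIPOR3 (-1.41), COL1A2 (-1.38), CCND2 (-1.37), S100A4 (-1.31), GAS1 (-1.27), LRRC17 (-1.22), SYTL2 (-1.21) and KRCC1 (-1.21). With BPAF, the effect of NPPB differed by 1.26, MAOA by 1.19, COL11A1 by 1.18, OLR1 by 1.18, CCN2 by 1.00 and ID1 by 0.82, and that of TXNIP by -1.36, MXD4 by -1.17, LOXL4 by -1.15, UBE2L6 by -1.07 and RIPOR3 by -1.03.

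Gene lists differed in the same sense by camera, given as the median log2 difference of effects. With BPA these were unfolded protein response and ATF4 genes (0.23), cholesterol synthesis (0.17), smooth muscle markers (0.14), fatty acid genes (0.12), ribosomal protein genes (-0.12) and interferon response genes (-0.32). With BPS they were heat shock (0.22), DNA replication, mitosis and cholesterol synthesis (0.16 each), interferon response (-0.14), NF-kB (-0.20) and matrix genes (-0.28). With BPAF they were mitosis (0.24), heat shock (0.17), immediate early (0.16), DNA replication (0.15), ribosomal protein and NF-kB genes (-0.13 each), metallothioneins (-0.31) and matrix genes (-0.34). With an estimated correlation 2 of these calls held, both with BPA: unfolded protein response (adjusted p = 0.0361) and cholesterol synthesis (adjusted p = 0.0214). Against control, the cholesterol median with BPA was -0.14 at 8 hours and 0.07 at 3 months, the latter without a camera call (adjusted p = 0.0533). The corresponding medians were -0.05 and 0.19 for unfolded protein response genes and 0.10 and -0.18 for interferon response genes. Quantile normalization took the ribosomal protein medians to -0.04 with BPA and -0.07 with BPAF and ended both calls (adjusted p = 0.647 and 0.118). It also ended those of the fatty acid (adjusted p = 0.0667) and smooth muscle lists (adjusted p = 0.264) with BPA and of heat shock with BPAF (adjusted p = 0.0516).

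Other splits of the same arrays were counted for each comparison. For the mean of the 3 bisphenols at 3 months, 1 of 100 splits, the real one, gave as many as 1802 probes, and the highest other gave 591. This excludes chance only if the arrays are independent samples, which the labels do not say; if each group came from 1 culture, the splits would not test it. The count was 492 without control replicate 2, and the splits were not run without it. At 8 hours all 100 splits reached the real count of 0, the highest at 47, and chance is not excluded. For the change of effect with time, 8 of 100 splits reached the real 569 with BPS (highest other 1092) and 8 of 100 the real 170 with BPAF (highest other 293), so by this count chance is not excluded. All 7 of the other splits concerned, for each compound, kept the 3-month arrays in their true groups and reshuffled the 8-hour arrays; among the splits that did not, the highest count was 1 for either compound. With BPA, 4 of 100 splits reached the real 1 probe, the highest other at 4. The other 3 of them likewise kept the 3-month arrays in their true groups (the highest count among the splits that did not was 0), so chance is not taken as excluded for 1 probe although the share is under 0.05.

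In comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. At 3 months against control the real and highest other counts were 101 and 0 for BPA, 2716 and 0 for BPS, and 1100 and 0 for BPAF, with 1 split as large in each, and 3677 and 0 for the controls of the 2 times, also with 1. Between compounds they were 432 and 2 for BPS and BPA at 3 months and 57 and 2 for BPAF and BPA at 8 hours (1 split each), and 2 and 17 for BPAF and BPA and 7 and 17 for BPAF and BPS at 3 months (2 splits each). Why a split of BPAF and BPA gave 17 probes against the real 2 was not tested. At 8 hours the real count was 0 for each compound against control (highest other 0), for BPS and BPA (highest other 0) and for BPAF and BPS (highest other 1), so that all 10 splits were as large.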

How the results depend on the processing

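The fit without the 4 arrays farthest from their group means (BPS replicates 1 and 3 at 3 months, BPAF replicate 3 and BPS replicate 1 at 8 hours) was chosen after seeing the data; the other alternatives were planned. Of 245 pairs of a named gene and a comparison past the threshold, 97 stayed past it with the same sign under every alternative, and 3194 of 3918 single checks did. The 1 reversal was MED7 between BPAF and BPA at 8 hours, at -0.02 with the probes of a gene averaged, where its probes differ. Counts under an alternative stayed within 1.5 times of the reported ones except as follows; the cause was not tested where none is given. Median centring shifted no value by over 0.0115 and so tested little. Quantile normalization shifted values by a median of 0.00344 and up to 0.192, gave 3 for BPAF against BPS at 3 months, ended 19 of 118 list calls, 8 of the 9 of ribosomal protein genes among them, and added 5. These scalings turned the median of 0 of the 118 called lists and moved the median over all probes by at most 0.013; the largest shift in the share of higher calls was -8.2 points.

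Without the filter on dim probes, which tests more probes, the counts at 3 months were 55 for BPA and 686 for BPAF against control, 196 for BPS against BPA and 1 for BPAF against BPS. BPAF against BPA at 8 hours gave 31, and the effects at 3 months against 8 hours 2 (BPA), 325 (BPS) and 65 (BPAF). The brightest 33.3% of probes gave 116 for BPAF against BPA at 8 hours. With only the groups compared, which leaves fewer arrays, BPA and BPS against control at 3 months gave 21 and 1662, each pair of bisphenols at 3 months 0, BPS against BPA at 8 hours 1, and the differences between times 6 (BPA), 314 (BPS) and 113 (BPAF). An intensity trend with robust variance gave 5 for BPS against BPA and 158 for BPAF against BPA at 8 hours, 4 for BPAF against BPA at 3 months and 3 for the BPA time difference. Array weights gave 253 for BPA against control, 654 for BPS against BPA and 5 for BPAF against BPA at 3 months, and 5 for the BPA time difference. With the probes of a gene averaged, BPA against control at 8 hours gave 1 and the BPA time difference 2. Without the 4 most deviating arrays, which leaves 1 BPS array at 3 months, assumed to vary like the other groups, BPA against control gave 1 at 8 hours and 176 at 3 months, and BPS against control at 3 months 520. BPS against BPA then gave 15 at 8 hours and 10 at 3 months, BPAF against BPA and against BPS 1 each at 3 months, and the BPS time difference 30.

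Arrays sharing a replicate number were taken as unpaired: the correlation of their deviations was over 0.1 for 0 of 18 pairs at 8 hours and 4 of 18 at 3 months (-0.24 to 0.24). With the number as a replicate block, BPAF against BPA and BPAF against BPS at 3 months gave 1 and 11, and the BPA and BPAF time differences 0 and 81. The other counts stayed within 1.5 times, as for BPA (73), BPS (2549) and BPAF (906) against control at 3 months.

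Leaving out each array in turn, which lowers precision, gave these ranges against control: BPA 0 to 5 at 8 hours and 11 to 92 at 3 months, BPS 0 to 0 and 1321 to 2396, BPAF 0 to 3 and 362 to 1050, and the mean of the bisphenols 0 to 1 and 492 to 1962. For BPS against BPA they were 0 to 11 at 8 hours and 11 to 618 at 3 months, for BPAF against BPA 11 to 157 and 1 to 15, and for BPAF against BPS 0 to 1 and 0 to 26. For the time differences they were 1 to 7 (BPA), 192 to 808 (BPS) and 28 to 262 (BPAF), and for the controls of both times 2135 to 3185. A pseudocount was not run because the values are logarithms. Signal over background limits the dim probes, which lie at the floor of the scale.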

Other observations

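The patterns and explanations below were chosen after the main comparisons had been seen; the criterion for each test was written before its value was known, except for the test with quantile normalization, which was set after its count and the median size of its shifts had been seen. The overlap of probes given with the 8-hour arrays was also added after seeing the data. Many genes that differed between the 8-hour and the 3-month control, by time or by any array batch that follows it, were found nearer to their 8-hour level in the 3-month bisphenol groups. RIPOR3 averaged 7.73 in the 8-hour control, 8.98 in the 3-month control and 8.16, 7.76 and 8.04 after 3 months of BPA, BPS and BPAF. LOXL4 averaged 8.93, then 10.57, and 10.02, 9.22 and 9.53. ID1 and ID3 went the other way: ID1 averaged 8.98 in the 8-hour control and 8.35 in the 3-month control, against 8.95, 9.44 and 9.25 with the 3 compounds, and ID3 averaged 9.84 and 8.91, against 9.64, 10.33 and 9.80. MAOA did not follow this, at 7.95 and 7.91 in the 2 controls and 8.69, 9.27 and 9.08 with the compounds. These genes were picked for this description after their values were seen. Some lists moved the same way by camera over time in the control and again in treated cells against the 3-month control: interferon response genes (median -0.16, then -0.18, -0.21 and -0.17 with BPA, BPS and BPAF), cholesterol synthesis genes (0.46, then 0.15 with both BPS and BPAF) and unfolded protein response genes (0.17, then 0.19 with BPA). Other lists went the opposite way: DNA replication genes (-0.20 in the control, then 0.19 with BPS and 0.11 with BPAF), mitosis genes (-0.23, then 0.13 with both) and nuclear receptors (0.12, then -0.08 with BPAF). Of all these calls, that of cholesterol synthesis in the control alone held with an estimated correlation, and that of mitosis genes with BPS ended after quantile normalization (adjusted p = 0.058). Of the probes called both for BPS at 3 months and for the change of the control, 984 had opposite signs and 25 and 58 were higher or lower in both, where independent lists would give 211, 95.9 and 115; for BPAF the numbers were 439 opposite and 20 and 26 alike.

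A shared 3-month control alone produces some of this opposition. Array noise of that control gave simulated covariances no lower than -0.00802 (BPA), -0.00749 (BPS) and -0.00871 (BPAF), and the observed ones were -0.0104, -0.0186 and -0.0127, which argues against noise as the whole of it. The correlations of -0.43, -0.46 and -0.38 were not stronger than the simulated means of -0.49, -0.50 and -0.50, and 34.9%, 34.7% and 36.9% of probes had the same sign against simulated 33.6%, 33.2% and 33.2%. A 3-month control out of place by itself would leave the difference between BPS and BPA, which uses no control array, unrelated to the change of the control, but their covariance was -0.00819 against a simulated range of -0.00429 to 0.00236, and -0.0107 to -0.00581 when each array was left out in turn; for BPAF and BPA it was -0.00226, within its simulated range of -0.00362 to 0.00329. This argues against the control as the whole cause of the BPS part, and it leaves a share of the control in the effects that all 3 compounds have in common open. A candidate explanation is that the treated cultures lay at different points of a change that long culture brings, which the lists neither bear out nor rule out as they went both ways, and an effect of the compounds and a separate history of each long-term culture cannot be told apart with the labels given.

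At 8 hours BPAF and BPA differed in interferon genes while no probe of either passed the threshold against control; as a list these genes lay higher in BPA (median 0.10) and lower in BPAF (median -0.14) than in control by camera, calls lost with an estimated correlation. Without BPAF replicate 3, which stood apart on the third principal component (20.18, the other arrays between -8.65 and 7.65), 11 probes passed, 9 of them among the 57 of all arrays, whose median absolute difference went from 0.49 to 0.47 and median SE from 0.0876 to 0.099. The count lies between the limits set for and against 1 deviating array and does not decide by itself. All 57 differences kept their sign and nearly their median size. Probes called with that array in the fit, and for a small spread between arrays, were likely to do so. This therefore does not decide either, and 1 deviating array stays open. The part of lost precision in the lower count was not tested. Differences in intensity left between arrays could be a source. Over the 57 probes, what quantile normalization removed came to a median of 0.968% of the difference and to 27.7% at most. That argues against differences between the distributions of whole arrays as the cause. Intensity differences confined to some probes would not be removed by it and stay open. What the deposited normalization itself did was not tested, and it stays open beside a difference between the compounds.

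The differences between BPS and control at 3 months may reflect a different share of dividing cells. The mean of 79 DNA replication and mitosis genes, centred over the arrays, was -0.24 to -0.10 in the 3-month control. It was -0.06 to 0.02 in BPS, against 0.07 to 0.13 in the 8-hour control. A higher mean was not particular to BPS: after 3 months it was -0.06 to -0.02 with BPAF and -0.16 to -0.06 with BPA. With that mean as a covariate, 7.6% of the count was left, 206 probes, 191 of them among the 2716. That met the limit set in advance in favour of this explanation, but the limit did not allow for lost precision, a point added after the value had been seen: over the 2716 probes the median absolute difference went from 0.37 to 0.29 and 99.9% kept their sign, while the median SE rose from 0.090 to 0.127. Smaller differences and a wider error both end calls, and their shares were not tested. Because the covariate differs between the groups, dividing cells and exposure cannot be told apart here.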
